A study of Mus musculus with 10 samples.

How the data were processed

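Total RNA of the right ventricle of 10 mice of strain 129SV was measured on 10 Affymetrix mouse expression arrays, 1 array per mouse. RNA was extracted with TRIzol and labelled as biotin-bearing cRNA, per the labels. The deposited values are linear signals in the unit intensity, made by the authors with MAS5 version 5.0, for 22690 probe sets. On every array the mean left after dropping the lowest and highest 2% of values was the same to within rounding, so each array had been scaled to 1 common level by the authors. The values carried no detection calls, and the scanner images and cell files were not used here. The number of arrays limits the precision. No time of dissection, array batch or hybridisation date was given in the sources used here.

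Mice were grouped by the labels into trained wildtype (n = 4), trained plakoglobin (+/-) (n = 4), untrained wildtype (n = 1) and untrained plakoglobin (+/-) (n = 1). Replicates were numbered in the order of their records, and the numbers are only names. Each trained group held 2 males and 2 females of 6 months. Both untrained mice were females of 10 months, so training cannot be separated from age. The series states that littermate pairs were used, but the labels do not say which mice were littermates, so no pairing entered the fits reported.

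Signals were raised to a floor of 104, the 10th percentile of all values, and log2 transformed with no further scaling. After 64 control probe sets were set aside, 13576 probe sets with a mean log2 signal at or above the 40th percentile were tested. Gene symbols came from the array annotation: 20393 probe sets carried 1 symbol, 691 carried several and 1606, of which 51 were controls, were not listed. A gene was represented by its brightest probe set with 1 symbol, which gave 8365 tested genes. Each log2 change and standard error (SE) given for a gene is that of its representing probe set unless another is named. The files name no genome build, so no positions are given.

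Linear models were fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. All tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genotype and sex were compared over the 8 trained mice in 1 fit with both terms, and the genotype by sex term was added in a further fit. Training was compared over all 10 mice with terms for genotype and sex, and the genotype by training term was added in a further fit. In the interaction fit each untrained group holds 1 mouse, which was assumed to vary like the others. The 2 untrained mice were also set against each other without a test. Jup was in addition compared by exact permutation tests over the 8 trained mice.

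Gene lists were tested with camera (limma) at an inter-gene correlation preset to 0.01, and again with an estimated correlation (statmod 1.5.0); fry was run beside it. The 22 lists held 299 genes, of which 274 were on the array. They covered hypertrophy and fetal genes, desmosome and intercalated disc, Wnt targets, adipogenesis, fibrosis, fatty acid oxidation, oxidative phosphorylation, glycolysis, calcium handling, ion channels, heat shock, immediate early genes, clock genes, growth signalling and cell cycle. The remaining lists were markers of endothelium, leukocytes, atrial myocytes, skeletal muscle, erythroid cells and lung epithelium, and sex-linked genes. Members are counted as past the threshold over all genes tested, and also with p values adjusted over the list alone.

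The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named are up to 10 genes per direction with the largest change among those past the threshold; where fewer than 5 per direction passed, the genes of lowest p fill up to 5 and are given as not past the threshold. Named too are up to 4 members of each list with the largest change, and Jup, Nppa and the sex-linked genes in every case. Further genes are named only where the text says that they were chosen after their values were seen, or as members of a list.

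The alternatives were quantile and cyclic loess normalization, no floor with a pseudocount of 1, a floor at the 25th percentile, no filter, a filter at the 60th percentile, eBayes without trend or with trend and robust, no sex term, all 10 mice in 1 fit for genotype and sex, females only or 1 genotype only for training, all probe sets of each gene for the lists, and each mouse left out in turn. Chosen after seeing the data were the fits without the 3 arrays whose ratio of the 3' to the 5' GAPDH control probe set was above 2, the same ratio as a covariate, a block by pairs guessed from neighbouring title numbers, and the gene lists compared by sex and by the genotype by training term. The calls were also checked on simulated data, in which 200 of 13576 probe sets were given a known change. Noise was drawn independently for each probe set and mouse. At a log2 change of 1, 22.4% were recovered by genotype, 14.9% by training and 23.9% by sex; at 2, these shares were 71.6%, 53.7% and 77.6%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.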

Results

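The data are right ventricular RNA signals of 10 mice, made to ask whether mice that carry 1 working copy of plakoglobin (Jup) respond to endurance training differently from wildtype mice. Plakoglobin is a protein of the desmosome and the adherens junction, the contacts that hold heart muscle cells together, and human mutations in it are linked to arrhythmogenic right ventricular cardiomyopathy. Training was daily swimming in water of 35 °C, 6 times per week, lengthened from 5 to 90 min. There were 4 trained wildtype mice, 4 trained plakoglobin (+/-) mice and 1 untrained mouse of each genotype, so values of an untrained group have no replicate.

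The median signal per array lay between 897.8 and 1150, and Pearson correlations between arrays across probe sets, which are not independent, lay between 0.842 and 0.944. The highest was between trained plakoglobin (+/-) replicate 1 and trained wildtype replicate 1. The first principal component, with 31.5% of the variance, set this pair of males apart from the rest. The ratio of the 3' to the 5' GAPDH control probe set, a measure of RNA integrity and of labelling, was 17.8 in trained wildtype replicate 2, 2.98 in trained plakoglobin (+/-) replicate 1 and 2.50 in trained wildtype replicate 1. On the remaining 7 arrays it lay between 0.849 and 1.02. The same ratio of the actin control was 3.05 in trained wildtype replicate 1 and 2.65 in trained plakoglobin (+/-) replicate 1. It was 1.29 in trained wildtype replicate 2, near the other 7 arrays at 0.932 to 1.24, so the actin control did not set that array apart. The second principal component, with 15.7% of the variance, did, at 63.6 against -25.1 to 6.92 on the other arrays. Trained wildtype replicate 2 also had the lowest median signal, 897.8, and the most values at the floor, 13%.

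The first comparison asked whether Jup RNA was lower in mice labelled plakoglobin (+/-). In trained mice the mean Jup signal, read by 1 probe set, was 2526 ± 680.1 in the arrays labelled plakoglobin (+/-) (SD, n = 4) and 3613 ± 653.9 in wildtype (SD, n = 4), and the ratio of their geometric means was 0.691. The difference did not pass a two-sided exact permutation test (p = 0.0857, n = 4 against 4, 70 labelings, smallest possible p 0.0286), nor an exact permutation within sex (p = 0.111, 36 labelings). In limma the log2 difference of -0.53 (SE 0.24) had an unadjusted p of 0.0485 and an adjusted p of 1. Among single arrays, trained plakoglobin (+/-) replicate 2, at 3519.9, lay within the range of the wildtype mice. In the untrained pair the order was the opposite: the array labelled plakoglobin (+/-) read 3156.9 and the array labelled wildtype 2386.8. Jup RNA did not separate the genotypes array by array, and all genotypes are given as labelled. Whether the probe set lies in the disrupted part of the gene is not given in the sources used here.

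**Figure D1:**
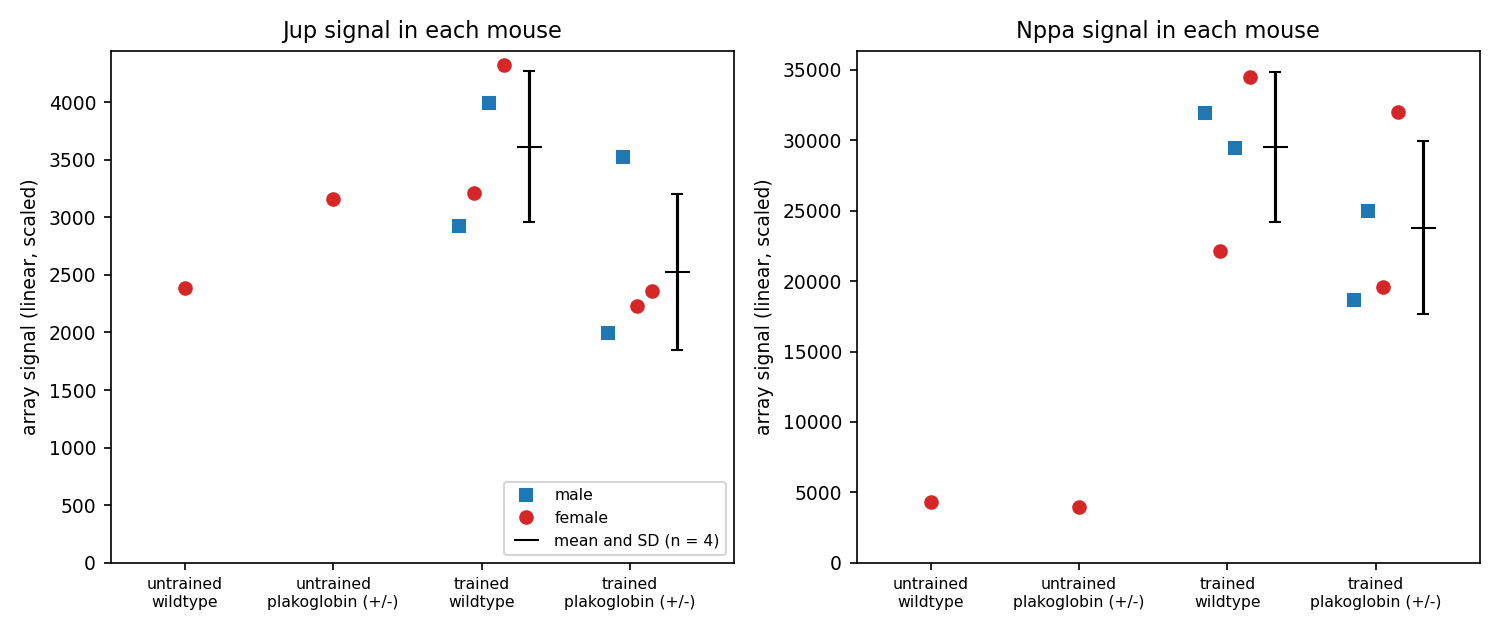
Array signals (intensity, linear axis) of Jup and Nppa for each of the 10 mice by group, males as squares and females as circles, with the mean and SD of the trained groups (n = 4 each). Jup signals of the genotypes overlap, and all 8 trained mice lie above both untrained mice for Nppa.

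The second comparison asked which genes differ by genotype in trained mice. No gene passed the test. The hypertrophy marker Nppa, which encodes atrial natriuretic peptide (ANP), read 29500 ± 5321 in trained wildtype (SD, n = 4) and 23800 ± 6157 in trained plakoglobin (+/-) mice (SD, n = 4), a log2 difference of -0.33 (SE 0.22). Apart from Jup, the desmosome and disc genes named here differed by at most 0.39 on the log2 scale. The desmosomal cadherin Dsc2 differed by 0.37 (SE 0.21) and Dsg2, another, by -0.29 (SE 0.19). Tmem43, a nuclear envelope protein linked to the same cardiomyopathy, differed by 0.39 (SE 0.20), and Ctnnb1, which encodes beta-catenin, the relative of plakoglobin that also carries Wnt signals, by -0.27 (SE 0.18). Of the Wnt targets, 7 of 8 tested were higher in the plakoglobin (+/-) mice, and this list did not pass either (camera, adjusted p = 0.234). Among them Axin2, a feedback inhibitor of the pathway, had 0.75 (SE 0.36) and Lgr5, a receptor for R-spondins, 1.13 (SE 0.69). Of the oxidative phosphorylation genes, 19 of 23 were lower, by a median of -0.07, among them Sdhc (-0.38, SE 0.24) and Cyc1 (-0.23, SE 0.13), subunits of respiratory complexes. This list had the lowest p of the 22 and did not pass (camera, adjusted p = 0.232).

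By limma 0 of 13576 probe sets passed, with a lowest adjusted p of 1, and 273 had an unadjusted p under 0.05, where 679 would be expected by chance. The genes of lowest p with higher signals in the plakoglobin (+/-) mice, none past the threshold, were Prelid3a (1.66, SE 0.43), U2af2 (1.16), a splicing factor, Sncb (0.73), Camk4 (0.96) and Prss12 (0.96). Those with lower signals were Atp5md (-0.94), Mybbp1a (-0.75), Alpk3 (-0.65), Pltp (-0.72), a lipid transfer protein, and Ptcra (-1.49). Prelid3a read 3276 ± 460.4 against 1204 ± 678.1 in wildtype and Mybbp1a 3767 ± 536.6 against 6351 ± 944.0 (SD, n = 4 each). On simulated data the same test recovered 71.6% of probe sets changed by 2 on the log2 scale but 22.4% of those changed by 1. The simulated noise was independent between probe sets and mice, which that of the arrays need not be. Large changes were also planted, which eases the adjusted threshold. These shares are thus likely too high for the real comparison and do not bound what it could have seen.

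None of the 22 lists passed by genotype with camera at either correlation, 0 members were past the threshold over all genes and 0 members of any list when adjusted over the list alone. With camera 4 lists had an unadjusted p under 0.05, and with fry 0 passed, with a lowest adjusted p of 0.635. Among hypertrophy and fetal genes (camera, adjusted p = 0.234) 9 of 12 were lower, such as the fetal isoform Acta1 (-0.58, SE 0.23) and the stretch-responsive Ankrd1 (-0.54, SE 0.43). Of the fibrosis and matrix genes (adjusted p = 0.272) 13 of 19 were lower, including the growth factors Tgfb3 (-0.78) and Ccn2 (-0.48). Of the desmosome and intercalated disc genes (adjusted p = 0.35) 12 of 15 were lower, by a median of -0.09. The glycolysis list (adjusted p = 0.364) held Hk1 at -0.46 and the glucose transporter Slc2a1 at -0.42. Single members of the fatty acid oxidation list (adjusted p = 0.842) went both ways, with Ucp3 at 0.56 and Mlycd at -0.39. The remaining lists had adjusted p values between 0.381 and 0.98. Examples from them are Fabp4 (adipogenesis, -0.19), Cacna2d1 (calcium handling, 0.61), Kcnh2 (ion channels, 0.55), Hspa5 (heat shock and endoplasmic reticulum stress, 0.36), Atf3 (immediate early, 0.61), Per1 (clock, -0.31), Cited4 (growth signalling, 0.65), Ccna2 (cell cycle, 0.54), Flt1 (endothelium, 0.54) and C1qa (leukocytes, 0.47). Single mice decided many of these values: of 87 named genes, 70 moved by over 1.5 times with 1 mouse left out, and 20 of these turned. With each mouse left out in turn Atf3 ranged from -0.39 to 1.65, C1qa from -0.21 to 0.85, Cited4 from 0.10 to 1.05 and Tgfb3 from -1.20 to -0.18. Lgr5 ranged from 0.26, without trained wildtype replicate 2 and its signal of 108.5, to 1.65. Ankrd1 ranged from -0.86 to -0.08, the latter without trained plakoglobin (+/-) replicate 1. Leaving out trained plakoglobin (+/-) replicate 1, or replicate 4, let 2 lists pass with lower signals in plakoglobin (+/-) mice. So did leaving out the 3 arrays of high GAPDH ratio, where they were oxidative phosphorylation and immediate early genes. These passes rest on the preset correlation of 0.01, as no estimated one was used with arrays left out. Over the 8 trained mice the estimate was 0.729 for immediate early genes and 0.148 for oxidative phosphorylation, so the preset makes their p values too small.

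The third comparison asked what differed between the 8 trained and the 2 untrained mice. Nppa, a marker of load on the heart, rose 6.33-fold, from 4350.5 and 3966.0 in the untrained mice to 26650 ± 6138 in the trained mice (SD, n = 8). Its log2 change was 2.66 (SE 0.26; adjusted p = 0.00112), and all 8 trained mice lay above both untrained mice. Larger still were the rises of Gdpd3, a phospholipid-cleaving enzyme, by 4.85 (SE 0.26; adjusted p = 1.76e-05), and of Pam, which amidates peptide hormones and is abundant in heart muscle, by 3.75 (SE 0.27; adjusted p = 0.000131). Among the genes that fell, H2-Aa (-3.00, SE 0.31), H2-Eb1 (-2.51, SE 0.32) and H2-Ab1 (-1.98, SE 0.25) encode class II antigen-presenting molecules. Cd74 (-2.12, SE 0.27) encodes their chaperone and H2-K1 (-2.83, SE 0.39) a class I molecule. Their adjusted p values lay between 0.00187 and 0.00727, and all 8 trained mice lay below both untrained mice at each. The list of fatty acid oxidation genes was lower as a whole, as was the list of leukocyte markers, and of the hypertrophy and fetal genes only Nppa passed out of 12 tested. Trained and untrained mice also differed in age, 6 against 10 months, and the males were all trained. Whether a difference in genetic background between them accounts for changes such as those of Gdpd3 or the H2 genes was not tested.

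By limma 85 of 13576 probe sets passed, 37 higher and 48 lower in trained mice, and 1178 had an unadjusted p under 0.05. By their representing probe set 24 genes rose and 21 fell; 8 of the 85 probe sets had no single gene name. The other genes with the largest rises were Timmdc1 (3.49), a factor in the assembly of a respiratory complex, Tmem87a (3.48), Kcnj14 (3.47), a potassium channel, and Gbp2b (3.43), an interferon-inducible GTPase. They were followed by Paip1 (3.34), Mboat2 (2.85) and Pygl (2.80), the liver isoform of glycogen phosphorylase, and their SEs lay between 0.306 and 0.541. The other genes with the largest falls were Pttg1 (-4.05, SE 0.32), also called securin, which restrains chromosome separation, Stk25 (-2.45), a kinase, Rsad2 (-2.27), an interferon-inducible antiviral protein, Gadd45gip1 (-1.71) and Lgals4 (-1.65). The adjusted p values of these 12 genes lay between 0.000249 and 0.0328, and all 8 trained mice lay beyond both untrained mice at each of these genes. The untrained signal of Tmem87a, Kcnj14, Gbp2b and Paip1 was at the floor in 1 of 2 mice, so their change depends on the floor. A further probe set of Paip1 gave -0.25, while a further probe set of Pttg1 gave -3.53. Of the further probe sets of H2-K1, those with -1.63 and -1.58 passed and one with -0.78 did not. For H2-Ab1 and Paip1, trained plakoglobin (+/-) replicate 1 stood apart from the other mice of its group.

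**Figure D2:**
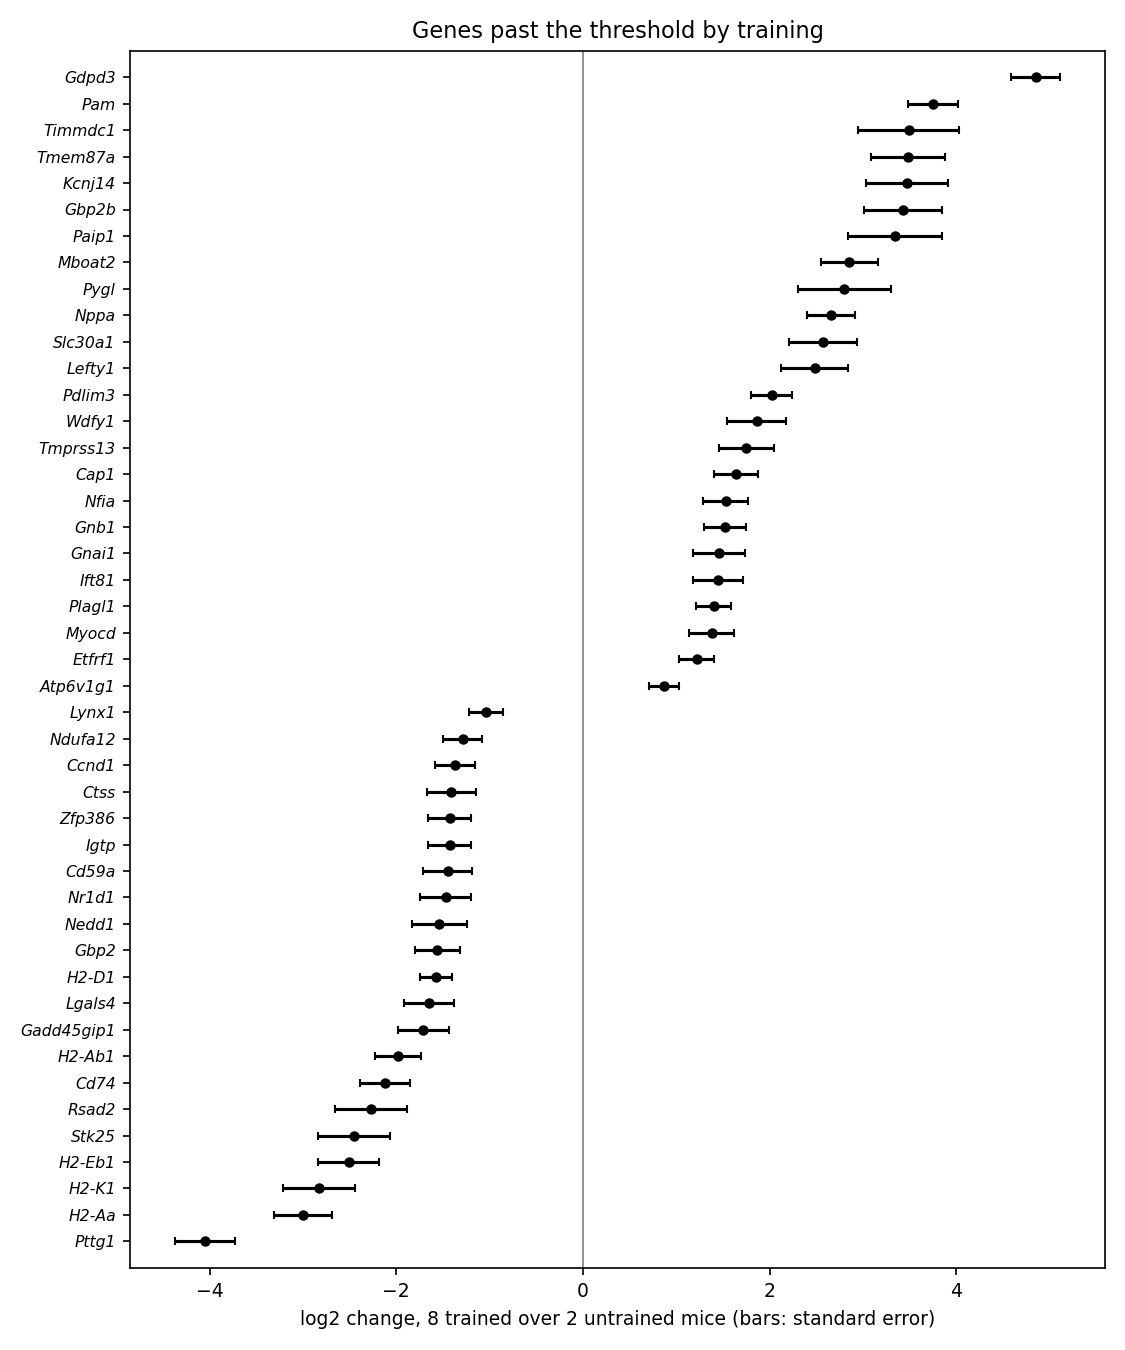
Log2 change with its SE of the 45 genes past the threshold, 8 trained over 2 untrained mice. The 24 genes to the right of 0 rose and the 21 to the left fell, from 4.85 for Gdpd3 to -4.05 for Pttg1.

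These calls rest on a pair of untrained mice: 10 probe sets passed without the untrained plakoglobin (+/-) mouse and 34 without the untrained wildtype mouse. Of the trained mice, 51 passed without plakoglobin (+/-) replicate 3, 53 without plakoglobin (+/-) replicate 4 and 50 without wildtype replicate 4, while 225 passed without the 3 arrays of high GAPDH ratio. Of the 22 named genes that passed, 5 stayed past the threshold with each of the 10 mice left out in turn, namely Gdpd3, Pam, Nppa, Tmem87a and Pttg1. The values of Timmdc1 and Paip1 moved by over 1.5 times, to 1.97 and 2.17 without the untrained wildtype mouse; without the other untrained mouse they were 5.00 and 4.50. Of the 75 named genes that did not pass, 49 moved by over 1.5 times with 1 mouse left out, and 10 of these turned.

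The fatty acid oxidation list was lower in trained mice by a median of -0.39 on the log2 scale, with 16 of 18 tested members lower (camera, adjusted p = 5.77e-05; adjusted p = 0.0466 with an estimated correlation). None of its members passed over all genes by their representing probe sets, and 4 fell when adjusted over the list alone. These were Angptl4 (-1.88, SE 0.53), a lipase inhibitor that fatty acids induce, Pdk4 (-1.26, SE 0.38), which restrains glucose oxidation, Ucp3 (-1.13, SE 0.34), a mitochondrial carrier, and Hadh (-0.90), an enzyme of beta-oxidation. A further probe set of Ucp3 passed over all genes (-3.38, SE 0.45). The leukocyte marker list was lower by a median of -0.64, with 9 of 10 lower (camera, adjusted p = 0.000206; adjusted p = 0.0466 with an estimated correlation). None of its members passed over all genes and 1 fell when adjusted over the list alone, the macrophage marker Adgre1 (-0.90, SE 0.23). The pan-leukocyte Ptprc had -1.30, the complement gene C1qa -1.25 and S100a9, of neutrophils, -1.08. The value of C1qa rests in part on trained wildtype replicate 2, an array of high GAPDH ratio with a C1qa signal of 731.6. Without it the value was -0.57. The desmosome and intercalated disc list was higher by a median of 0.26, with 11 of 15 higher, among them Perp (0.80, SE 0.23), Ctnna1 (0.57), Pkp4 (0.53) and Pkp2 (0.44), desmosomal or adherens junction proteins. It passed narrowly with camera (adjusted p = 0.0494) and was lost with an estimated correlation (adjusted p = 0.202), and 0 of its members passed over all genes or when adjusted over the list alone. With camera it was also lost under several alternatives, among them those without 1 or the other untrained mouse. Losses also came without trained wildtype replicate 2 (adjusted p = 0.105) or 3 (0.0562), or trained plakoglobin (+/-) replicate 4 (0.0967). Without the 3 arrays of high GAPDH ratio the adjusted p was 0.0725.

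**Figure D3:**
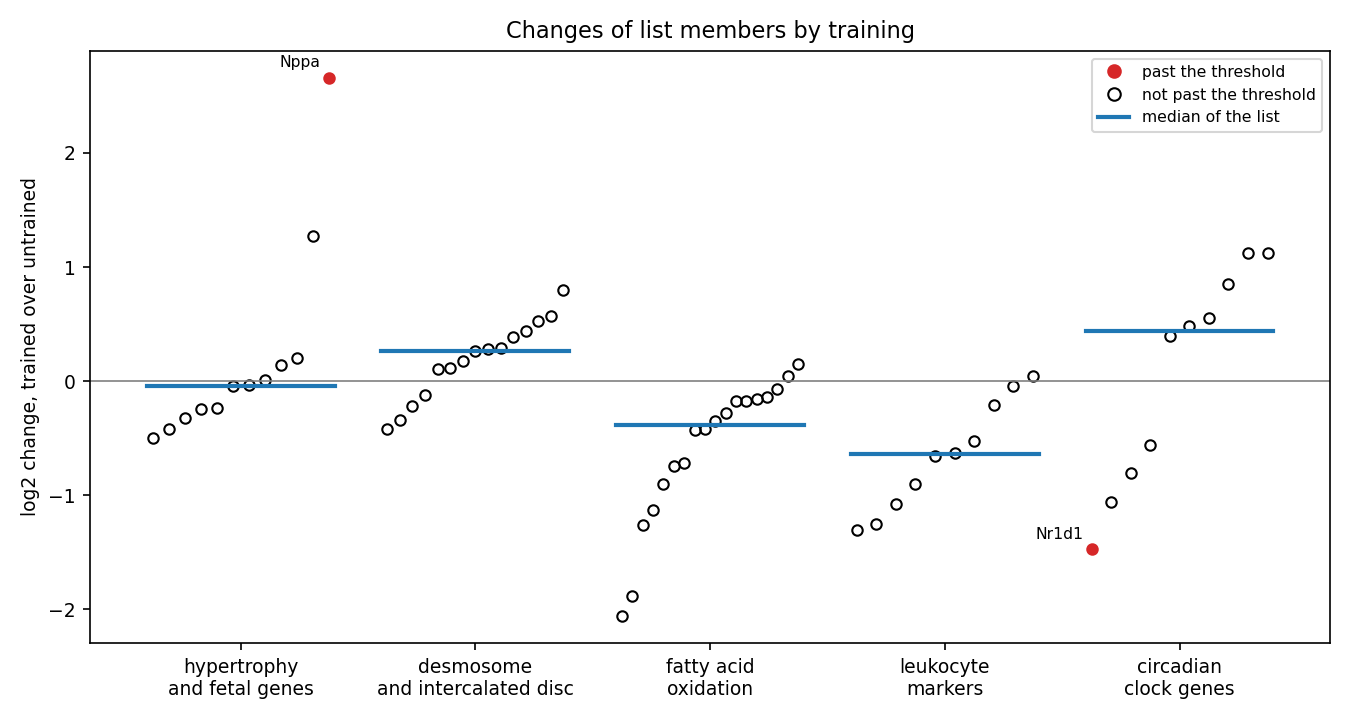
Log2 change by training (8 trained over 2 untrained mice) of each tested member of the hypertrophy and fetal, desmosome and intercalated disc, fatty acid oxidation, leukocyte and clock gene lists; filled red points passed the threshold over all genes and the blue line is the list's median. Of these members only Nppa, at 2.66, and Nr1d1, at -1.47, are filled.

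The other 19 lists did not pass with camera at either correlation. With fry, which tests whether the genes of a list move on balance one way, these 3 lists and the lung epithelium markers (adjusted p = 0.0473) passed. Of 12 hypertrophy and fetal genes (adjusted p = 0.811) 1 rose, Nppa, also when adjusted over the list alone. Myh7, the fetal myosin heavy chain, had 1.27 (SE 0.60), or 0.66 without trained plakoglobin (+/-) replicate 4, Acta1 -0.50 and Nppb, the B-type peptide, -0.42. The list's median was -0.04, its mean 0.21 and its test direction upward. Of 10 clock genes (adjusted p = 0.443) 1 fell over all genes, Nr1d1 (-1.47, SE 0.27; adjusted p = 0.0405; lower in 8 of 8 trained mice), a repressor of the clock. When adjusted over the list alone it fell and 3 rose, Hlf (1.12, SE 0.25), Per1 (1.12, SE 0.39) and Tef (0.86), while Arntl, the clock's activator, had -1.06. Of 19 fibrosis and matrix genes (adjusted p = 0.12) 0 passed over all genes. Adjusted over the list alone, 1 rose, Ccn2 (1.79, SE 0.44), and 2 fell, the matrix genes Postn (-1.35) and Col3a1 (-1.05). Of 8 Wnt targets (adjusted p = 0.431) 1 fell on both adjustments, the cell cycle regulator Ccnd1 (-1.37, SE 0.22; adjusted p = 0.015; lower in 8 of 8), whose further probe sets had -0.69 and -0.66 and did not pass.

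Among the metabolic and excitation lists, 0 members passed over all genes. Oxidative phosphorylation had an adjusted p of 0.134 with 13 of 23 genes lower, among them Sdha (-0.40) and Sdhb (-0.38), subunits of succinate dehydrogenase. Glycolysis had 0.741, with Slc2a4, the insulin-responsive glucose transporter, at 0.32. In these lists, and in the calcium handling, adipogenesis, growth signalling, heat shock and cell cycle lists, 0 members passed when adjusted over the list alone. The calcium handling list had an adjusted p of 0.474, with the release channel Ryr2 at 0.54 and its partner Casq2 at -0.36. Of the ion channels (adjusted p = 0.511) 1 rose when adjusted over the list alone, the potassium channel Kcnd2 (0.82, SE 0.19). Adipogenesis had 0.431, with Lipe, a lipase, at -0.76, and growth signalling 0.741, with the receptor Igf1r at 2.01 (SE 0.69). The value of Igf1r rests on the untrained plakoglobin (+/-) mouse, whose signal of 93.5 was under the floor: it was 0.20 without that mouse and 3.82 without the untrained wildtype mouse. The heat shock list had 0.817, with Hspb1 at -0.50 and Dnajb1 at 0.51; its median and mean were above 0 and its test pointed down. Immediate early genes had 0.172, and 1 fell when adjusted over the list alone, Ier2 (-1.16, SE 0.29), after the sex term. Cell cycle genes had 0.865, with Pcna at 0.20.

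Among the markers of other cell types, the endothelial list had an adjusted p of 0.365 with 1 member that fell when adjusted over the list alone, the receptor Kdr (-1.03, SE 0.29). The atrial myocyte list had 0.103: Nppa, which it shares with the hypertrophy list, rose on both adjustments, while the other atrial genes Myl4 (0.19), Bmp10 (-0.12) and Stard10 (0.03) did not pass. The lung epithelium list had 0.103, and of its 2 tested members Sftpb (-0.73, SE 0.27) fell when adjusted over the list alone. Skeletal muscle markers had 0.596 (Myl1 -0.50), erythroid markers 0.474 (Alas2 -0.92) and the sex-linked genes 0.452 (Xist 0.37), with 0 members past the threshold on either adjustment.

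The fourth comparison asked whether the training effect differed between genotypes. In the fits to each genotype alone, with 4 trained mice and 1 untrained mouse, Nppa was higher in trained mice by 2.67 in wildtype and by 2.66 in plakoglobin (+/-) mice. Neither passed alone, and the difference between genotypes in the joint fit, which shares 1 sex term, was -0.19 (limma, adjusted p = 1). By limma 0 of 13576 probe sets had a training effect that differed by genotype, with 434 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0711. The genes of lowest p with a more positive change in plakoglobin (+/-) mice, none past the threshold, were Gpaa1 (3.86), Ocel1 (3.44), Slc6a9 (2.93), a glycine transporter, Igf1r (3.62) and Bmerb1 (2.55). Those with a more negative change were Timmdc1 (-3.03), Kcnmb1 (-3.54), Camk4 (-2.97), a kinase, Usp29 (-3.01) and Dlx4 (-2.90). The lower untrained signal was under the floor for Igf1r (93.5) and Usp29 (49). It was near the floor for Ocel1 (138), Kcnmb1 (138.5) and Camk4 (158), and between 198.5 and 596.6 for the other genes named. Much of the size of these values thus rests on dim readings of single untrained arrays. With no filter on dim probe sets 66 passed, 23 with a more positive and 43 with a more negative change in plakoglobin (+/-) mice. Without trained wildtype replicate 1, or without the 3 arrays of high GAPDH ratio, 1 probe set passed. Across all 13576 probe sets, which are not independent, the changes of the genotypes had a Pearson r of 0.282 and a Spearman rho of 0.235. Each genotype had 1 untrained mouse, and Jup did not follow the labels in that pair.

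The lists were compared for this term only after the data were seen. With camera 2 of 22 passed, both with a more negative change in plakoglobin (+/-) mice. The fibrosis and matrix list had a median difference of -0.40, with 16 of 19 members below 0 (adjusted p = 0.0456; adjusted p = 0.581 with an estimated correlation). The oxidative phosphorylation list had -0.19, with 18 of 23 below 0 (adjusted p = 0.0456; adjusted p = 0.785 with an estimated correlation). Its size rested on the scaling, at -0.05 with quantile normalization (adjusted p = 0.806) and -0.07 with cyclic loess (adjusted p = 0.895). The fibrosis list had -0.37 and -0.38 and was lost with both (adjusted p = 0.115 and 0.158). Of their members 0 passed over all genes or when adjusted over the list alone, and with fry 0 lists passed, with a lowest adjusted p of 0.13. In the untrained pair the plakoglobin (+/-) array was higher by a median of 0.28 for the fibrosis list and 0.16 for oxidative phosphorylation. In trained mice the genotypes differed by -0.12 and -0.07. Much of both differences thus rests on 1 untrained array of each genotype. The fits to each genotype alone use the same arrays and are no further support. In them the fibrosis list changed with training by a median of -0.54 in plakoglobin (+/-) mice and -0.06 in wildtype mice. The oxidative phosphorylation list had -0.21 and 0.04 in the same fits, each with 1 untrained mouse. Both lists were lost without trained wildtype replicate 2 (0.109 and 0.145), trained wildtype replicate 4 (0.111 for both) or trained plakoglobin (+/-) replicate 3 (0.0923 and 0.228). The fibrosis list was also lost without trained wildtype replicate 3 (0.0753) or trained plakoglobin (+/-) replicate 4 (0.0744), and the other list without trained plakoglobin (+/-) replicate 2 (0.0705). The other 20 lists did not pass, with a lowest adjusted p of 0.202, and 1 member of the growth signalling list passed when adjusted over its list alone.

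The untrained mice, of 1 array per genotype and without a test, differed at least 2-fold in 581 of 8365 genes, where the 28 pairs of trained mice differed in 457 to 1273. The array labelled plakoglobin (+/-) was higher for Camk4 (3.93), Elovl7, a fatty acid elongase (3.81), Kcnmb1, a subunit of a calcium-activated potassium channel (3.68), Fgfr4 (3.54) and Egr4 (3.32). It was lower for Pcyt2, an enzyme of phosphatidylethanolamine synthesis (-3.82), Bcl11a (-3.45), Pik3cg (-3.32), Stc1 (-3.27) and Gpaa1 (-3.27). Apart from Gpaa1, whose lower signal was 555.1, the lower signal of each of these genes lay between 129.5 and 182, near the floor. The size of their differences thus rests on a single dim reading each. Picked by rank among random lists of genes, the fibrosis list had a median of 0.28, oxidative phosphorylation 0.16 and the leukocyte markers -0.25. The other lists so ranked had medians from -0.265 to 0.183. That ranking holds no spread between mice, so it does not mark a genotype difference. The same 2 arrays enter the genotype by training term.

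The fifth comparison set males against females among the trained mice. Immediate early genes, which are switched on within minutes of a stimulus, were higher in males. Fos was higher by 5.91 (SE 0.66; adjusted p = 0.0176), at 393.6 ± 215.4 in females (SD, n = 4) and 28690 ± 23300 in males (SD, n = 4). Egr1 was higher by 4.35 (SE 0.48), Nr4a1 by 3.25 (SE 0.42), the phosphatase Dusp1 by 2.72 (SE 0.33), Zfp36, which destabilises mRNA, by 2.62 (SE 0.33), and Ier2 by 2.25 (SE 0.25). The mean log2 signal of the 12 immediate early genes was 13.41 ± 0.97 in males and 10.46 ± 0.23 in females (SD, n = 4 each). The difference of 2.95 was the most extreme of the 35 splits of the 8 trained mice into groups of 4 (exact permutation p = 0.0286, the smallest possible, with the 8 mice taken as independent). It was 14.50 and 13.95 in the males trained plakoglobin (+/-) replicate 1 and trained wildtype replicate 1, whose GAPDH and actin ratios and 5' control signal for 18S ribosomal RNA were also raised. It was 12.44 and 12.75 in the other males and 10.82 and 10.75 in the untrained females. Xist, the RNA that silences the inactive X chromosome, was lower in males by -3.34 (SE 0.23; adjusted p = 0.000764), at 1340 ± 255.1 against 13700 ± 3200 (SD, n = 4 each). Eif2s3y, a gene of the Y chromosome, read 3293 ± 1328 in males and 68.75 ± 91.01 in females (SD, n = 4 each), with 3 of 4 females under the floor; it was too dim on average to be tested. The Y-linked Kdm5d (-0.06) and Uty (0.26) were dim in both sexes.

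By limma 7 of 13576 probe sets passed, these 6 immediate early genes and Xist, with adjusted p values of 0.0176 to 0.0378 for the former, and 1198 had an unadjusted p under 0.05. The genes of next lowest p with higher signals in females, none past the threshold, were Atp5md (-1.14), Plagl1 (-0.84), Dynlrb1 (-0.82) and Epha4 (-1.20). Without trained wildtype replicate 1, 2 or 4, or trained plakoglobin (+/-) replicate 3 or 4, 1 probe set passed, Xist; without the 3 arrays of high GAPDH ratio 17 passed, the 7 included. By limma 0 of 13576 probe sets had a genotype effect that differed by sex, with 361 at an unadjusted p under 0.05 and a lowest adjusted p of 1. The genes of lowest p were Col25a1 (3.60), Tex264 (2.30), Edem1 (3.10), Gripap1 (1.74) and Bmp7 (3.55), and Acad10 (-3.07), Lama5 (-1.94), Dyrk1b (-2.11), Cys1 (-2.87) and Rap2b (-1.98).

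The lists compared by sex were chosen after the data were seen. Of 12 immediate early genes 6 rose over all genes and 11 when adjusted over the list alone, among them the transcription factors Junb (3.16), Jun (1.69) and Atf3 (3.90) (camera, adjusted p = 2.42e-26; adjusted p = 0.0666 with an estimated correlation). The fibrosis and matrix list was higher in males by a median of 0.39, with 16 of 19 higher (adjusted p = 0.000132; adjusted p = 0.0608 with an estimated correlation). Of its members 0 passed over all genes and 4 rose when adjusted over the list alone, Col3a1 (1.38), Postn (1.15), Col5a1 (0.68) and Sparc (0.53). The leukocyte list was higher with 10 of 10 members (adjusted p = 0.000837; adjusted p = 0.0666 with an estimated correlation). Of these 0 passed over all genes and 3 rose when adjusted over the list alone, Cd14 (1.29), Csf1r (0.64) and Adgre1 (0.62). The sex-linked list passed on its 1 tested gene, Xist (adjusted p = 6.53e-06; adjusted p = 0.0608 with an estimated correlation). The other 18 lists did not pass, with a lowest adjusted p of 0.191.

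**Figure D4:**
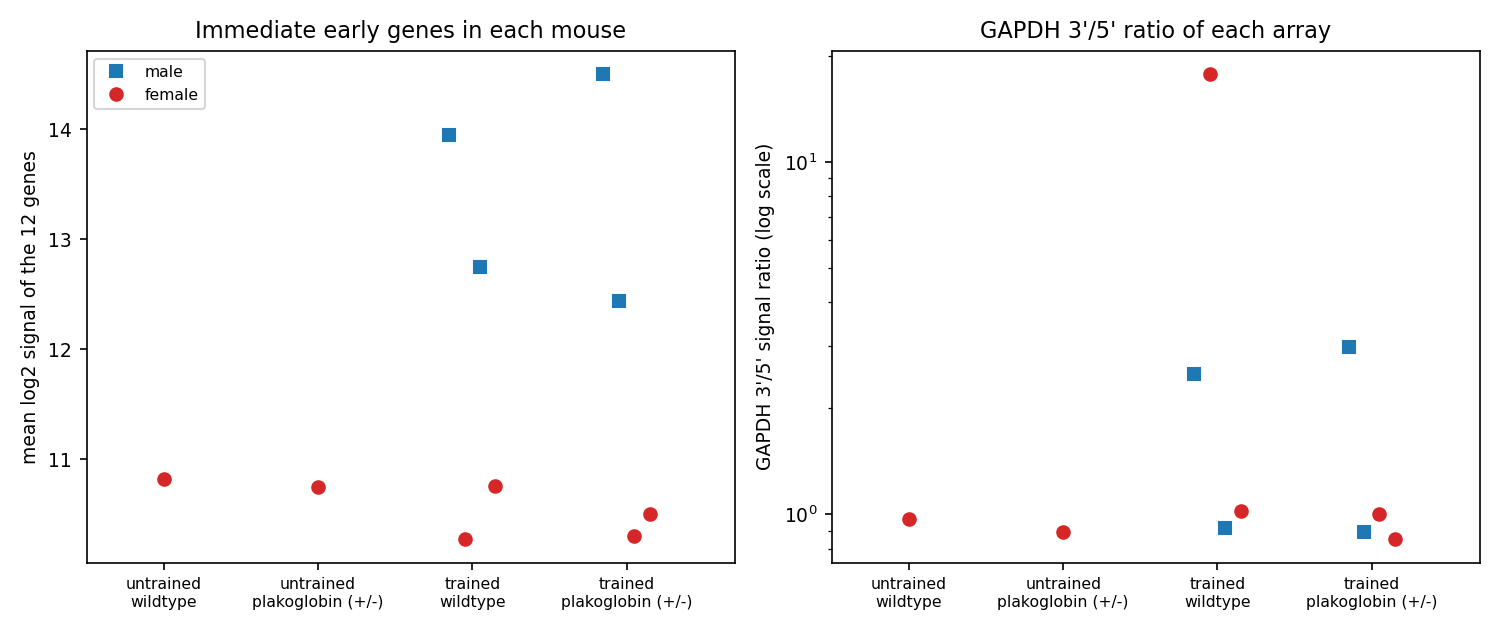
Mean log2 signal of the 12 immediate early genes per mouse (males as squares, females as circles) and the ratio of the 3' to the 5' GAPDH control probe set per mouse, on a log axis. The 4 trained males lie above the 4 trained females in the first panel, and 2 of those males and 1 female have a ratio above 2.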

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

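Chosen only after the result was seen were the tests of a sequence difference under single probe sets, of fewer leukocytes, of RNA quality as the whole cause in males, and of other splits by the count at an unadjusted p, by the lists by sex and by the largest difference of any list's mean, the fits without the 3 arrays of high GAPDH ratio, and the added lists of antigen presentation and interferon genes. Of 64 groups of values tested for a sample far from the others, 4 held one, where chance gives about 3.2. The log2 signal of Paip1 was 10.75 in trained plakoglobin (+/-) replicate 1 against a median of 11.18 in the other mice of its group. The log2 signal of H2-Ab1 was 11.43 in the same mouse against 10.68. The ratio of the 3' to the 5' GAPDH control probe set was 17.8 in trained wildtype replicate 2 against 1.02, and 2.98 in trained plakoglobin (+/-) replicate 1 against 0.892. The 5' control probe set for 18S ribosomal RNA, which no comparison used, read 21828 in trained plakoglobin (+/-) replicate 1 and 19847 in trained wildtype replicate 1, more than 10 times the highest untrained signal of 1614. Trained wildtype replicate 4 (6190.3) and replicate 3 (2549.3) also lay above it, and the 3' probe set for the same RNA was highest in trained wildtype replicate 4 (170545.7).

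The first pattern is the size of the changes between trained and untrained mice, such as Gdpd3 and Pttg1. RNA quality as the whole cause was not decided. The median size of the change at the 85 probe sets was 1.98 with all 10 arrays and 1.97 without the 3 arrays of high GAPDH ratio. That is a ratio of 0.993, with the same sign in 85 of 85. But these probe sets were called with the 3 arrays included, and 84 of 85 had all 8 trained mice beyond both untrained mice. Size and sign were thus nearly fixed in advance. The values show only that the 3 arrays did not carry these calls. A sequence difference between the mice under single probe sets may account for part: of 40 genes with a further tested probe set, 17 (42.5%) had one that moved by under 0.25 of the called change, as at Paip1, which leaves it open, and a difference in genetic background that acts on whole genes was not tested. Age and training cannot be told apart, because 0 untrained mice had the trained mice's age, and for the count of probe sets chance cannot be excluded, as 4 of the 45 ways to set 2 mice against 8 gave at least the real 85; this says nothing of single genes such as Gdpd3, past the threshold with each of the 10 mice left out. The highest other count, 853, came from setting apart trained plakoglobin (+/-) replicate 1 and trained wildtype replicate 1 (or, alike, the other males), and 154 came from the former with trained wildtype replicate 2, which points to a structure of the samples; without these 3 arrays the real comparison gave 225.

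The second pattern is the fall of antigen presentation genes in trained mice. A lower interferon response is a candidate explanation: the 25 tested interferon-inducible genes outside the MHC that had not passed had a median log2 change of -0.48, with 21 of 25 lower (camera, p = 8.85e-06; p = 0.00872 with an estimated correlation). Against it stands Gbp2b, an interferon-inducible gene that rose by 3.43. Fewer leukocytes of all kinds cannot be told apart from it, since the leukocyte markers fell by a median of -0.64 and the class II genes by -2.05, a ratio of 0.312, but the difference of the means, 0.99, was within 2 standard errors of 0.584. Age, training, and a difference in MHC type between the mice, which the labels do not give, stay open as untested.

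The third pattern is the high level of immediate early genes in trained males. RNA quality as read by the GAPDH ratio is argued against as the whole cause, since all 6 genes also passed without the 3 arrays of high ratio, and the males of ratio 0.892 and 0.916 had list means of 12.44 and 12.75 against 10.76 in the highest trained female. A part stays open, because without the 3 arrays the median went from 2.67 to 1.82, a ratio of 0.681, and 2 of them are the males with the highest levels. Chance is not excluded. With the 8 trained mice taken as independent, the real split ranked first of 35 for the list's mean, the smallest p that 35 splits allow. The list was singled out after its values were seen. Its difference of 2.951 was reached by the largest difference of any list but the sex-linked one in 1 of 35 splits. The highest other split gave 2.11. The immediate early list alone gave the same 2.951 and 2.11, so this check corrects little for the choice of the list. For the count of probe sets 1 of 34 splits gave the real 7, with 0 as the highest other. As the 7 include Xist, which follows sex by itself, the real split ranked first whatever the immediate early genes did. The series states littermate pairs, but the labels do not say which mice they were. If the guessed pairs, each of 1 sex, were the units, the 3 possible splits would be too few. For the count of lists chance cannot be excluded either, as 3 of 34 splits gave at least the real 4, with 4 as the highest other. Sex itself stays open, as does handling or the order of dissection, which the labels do not give and no test covered.

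For genotype in trained mice the real counts were 0 probe sets (highest other split 4) and 0 lists (highest other 3), so that all 34 splits reach them by construction and say nothing about chance. At an unadjusted p under 0.05, 29 of 34 splits gave at least the real 273, so chance cannot be excluded, and the highest other, 2401, points to a structure of the samples other than genotype. For the lists by training, 6 of 45 splits gave at least the real 3, with 4 as the highest other, so chance cannot be excluded there.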

How the results depend on the processing

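Chosen only after the data were seen were the fits without the 3 arrays of high GAPDH ratio and with that ratio as a covariate, a block by guessed pairs, and the lists by sex and by the genotype by training term. Every count by genotype of probe sets, and every count by genotype and sex, stayed at 0 in all alternatives. Of the values of single genes under the alternatives, 2170 by training kept their side of the threshold, 104 were weaker and 10 stronger. By sex 271 did, 44 were weaker and 6 stronger, and by genotype all 1806 did. Only genes that had passed could become weaker. As 75 of the named genes by training, 10 by sex and 87 by genotype had not passed, these counts overstate how stable the calls were. Of the values of the lists past the threshold, 66 by training kept it and 12 were weaker, and by sex 78 did, 5 were weaker and 1 turned; by the genotype by training term 20 did and 24 were weaker. Scaling moved the median training change little, to 0.015 at most. Signals near the floor limit the dim genes, and the cause of each change below was not tested unless one is given. No paired analysis was possible because the labels do not say which mice were littermates and the groups share no number. As a guess, mice with neighbouring title numbers, and the remaining male of each genotype, were taken as pairs: with these as a block limma gave 0 probe sets by genotype, with 570 at an unadjusted p under 0.05, camera gave 0 lists, and Jup had -0.53 (limma, unadjusted p = 0.0158). The deviations of the guessed pairs from their group means correlated at 0.04 to 0.54, and 3 of the 4 wildtype mice correlated best with the guessed partner; as each pair is of 1 sex, sex enters these values too, and they are a hint from the data and not from the design.

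Jup in trained mice had an unadjusted p past the threshold in the fit reported and not with no filter (-0.53), eBayes without trend (-0.53) or all 10 mice (-0.35); with each mouse left out it ranged from -0.73 to -0.40 and passed in 2 of 8 fits. In all it passed in 12 of 21 alternatives. Lists by genotype were 0, but 2 without the 3 arrays and 0 to 2 with each mouse left out. Probe sets by training were 85, but 1 in wildtype mice only and 2 in plakoglobin (+/-) mice only, where fewer samples were fitted, 225 without the 3 arrays, of which 83 were shared, and 10 to 87 with each mouse left out, which can leave a lone untrained mouse assumed to vary like the others. Nppa by training was 2.67 in wildtype mice only (adjusted p = 0.226) and 2.66 in plakoglobin (+/-) mice only (adjusted p = 0.331), no longer past the threshold with fewer samples, in a range of adjusted p from 3.51e-05 to 0.331; with each mouse left out it ranged from 2.50 to 2.81 and stayed past it. Lists by training were 3, but 5 with a filter at the 60th percentile, 5 in plakoglobin (+/-) mice only and 2 to 5 with each mouse left out; fatty acid oxidation and leukocyte markers passed under all 26 alternatives.

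Probe sets with a training effect that differed by genotype were 0, but 1 with quantile normalization, 66 with no filter, 1 without the 3 arrays, 1 with the guessed pairs as a block and 0 to 1 with each mouse left out. Lists with such an effect were 2, but 0 with quantile or cyclic loess normalization, no filter, no sex term, an estimated correlation, all probe sets of each gene or the GAPDH ratio as a covariate, 1 with a filter at the 60th percentile and 0 to 2 with each mouse left out. Probe sets by sex were 7, but 13 with quantile normalization, 15 with a floor at the 25th percentile, 2 with no filter, 11 with a filter at the 60th percentile, 1 with eBayes without trend, 15 with all 10 mice, 17 without the 3 arrays, 16 with the GAPDH ratio as a covariate and 1 to 12 with each mouse left out. Lists by sex were 4, but 0 with an estimated correlation, 7 with all probe sets of each gene and 4 to 5 with each mouse left out. The median of the sex-linked list by sex turned from -3.34 to 0.101 with no filter, because that setting adds dim genes of the Y chromosome to Xist.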

Other observations

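Chosen only after the result was seen were the added lists of antigen presentation and interferon genes, and the test of time of day. In trained mice, the genes that load and present peptides to T cells were lower as a group. Of 6 tested class II genes 4 fell over all genes, with a median log2 change of -2.05 (camera, p = 8.38e-12; p = 0.000607 with an estimated correlation). Of 9 tested class I and peptide loading genes 2 fell, H2-K1 and H2-D1, all 9 were lower by their representing probe sets, and the median was -1.57 (p = 0.00047 with an estimated correlation); of the further probe sets of H2-D1, those with -2.17 and -1.74 passed and one with 0.37 did not. B2m, the light chain of class I, had -1.65 and a further probe set that passed (-2.23), while the proteasome subunit Psmb9 had -1.64 and the peptide transporter Tap1 -1.23. Of 30 tested interferon-inducible genes outside the MHC 3 fell, the GTPases Igtp (-1.43) and Gbp2 (-1.56) and the antiviral Rsad2 (-2.27), and 1 rose, Gbp2b (3.43). In all 25 of the 30 were lower, with a median of -0.51 (camera, p = 1.01e-07; p = 0.00328 with an estimated correlation). Higher but not past the threshold were Samhd1 (0.99) and Oas1a (0.97), and Ciita (0.88) of the class II list. These lists were drawn up from the same data, so they are not independent evidence.

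Of the 85 probe sets past the threshold by training, 84 had all 8 trained mice beyond both untrained mice. As the 85 were called for this difference, that count is no further support. Of all 13576 tested probe sets 1255 (9.24%) were so separated. The mean share over all ways to set 2 of the mice against 8 is 4.44%. How far single pairs spread around that mean was not tested, so no excess is read from it.

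A hypothesis on the clock genes is that the trained and untrained mice were dissected at different times of day. The mean change of Per, Dbp, Tef and Hlf genes minus that of Arntl and Clock was 1.64, which 1 of 45 splits of the 10 mice reached, with 1.348 as the highest other. Nr1d1, the clock gene past the threshold (-1.47), was in neither group; it shares its activator with Dbp but went the other way, and with Nr1d1 placed beside Dbp the difference was 1.26, which 1 of 45 splits reached, with 1.151 as the highest other. A shift in clock phase could give such a difference, but training or age may move these genes alike. Whether the fall of Nr1d1 goes with or against such a shift was not tested, as a shared activator does not fix the hour of its peak. Npas2 and Per2 were too dim to be tested, and no time of dissection was given in the sources used here.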
